A study of Mus musculus with 24 samples.

How the data were processed

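RNA was sequenced from 24 libraries of dendritic cells sorted from mouse spleen. Per the labels, the mice were F1 animals of a C57BL/6 by FVB/N cross, and their Flt3 genotype was either +/+ (WT) or ITD/+ (ITD, the internal tandem duplication). The labels name 5 sorted subsets: PDC, canonical CD8+ (C_CD8), non-canonical CD8+ (NC_CD8), Esam-hi CD11b+ (Esamhi) and Esam-lo CD11b+ (Esamlo) cells. They also give 4 experiment batches, A to D, and per the series design text the replicates came from independent experiments. Batches A and B held the PDC libraries, B, C and D those of both CD8+ subsets, and C and D those of both CD11b+ subsets. Each held 1 WT and 1 ITD library of each of its subsets: 12 pairs, perhaps dependent within a batch.

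Per the labels' protocols, cells were sorted by flow cytometry, RNA was purified with PicoPure columns (in some samples after Trizol), cDNA was made with the SMART-seq v4 Ultra Low Input kit and libraries with a low input kit from Clontech. Per the submitters' processing notes, the tools included bcl2fastq 1.8.4, Bowtie2 and DESeq2 1.8.2, with the mm10 genome build. The version listed for Bowtie2, 0.4, is not a numbering of its releases. The read counter, the gene annotation and the strandedness are not given in the sources used here. The authors deposited a table of raw read counts per Ensembl gene for all 24 libraries, and these counts were the values analysed. The authors also deposited a table of normalized signal, which was not used for any test. This deposited signal was checked against the counts: within each library it was the count divided by a single size factor, to a relative spread of at most 1e-14. The factors ran from 0.634 to 1.3 and differed by at most 4.44e-16 (relative) from size factors recomputed from the counts by DESeq2's rule. The normalized table held 26275 genes, and the 1267 genes with reads that it left out had a total of 1 count each.

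Symbols, positions and gene types came from a mouse annotation of the same genome build as mm10. Of 39017 genes in the count table, 37607 had a symbol there, and the 1410 without one held 0.598% of all counts. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for plots. Counts were scaled with TMM factors and filtered with filterByExpr (minimum count 10), which left 18093 genes. A single edgeR quasi-likelihood model with 10 group means, 1 for each subset and genotype, was fitted to all 24 libraries, with no block and 14 residual degrees of freedom. The common biological coefficient of variation was 0.317. A gene was called when its Benjamini-Hochberg adjusted p, over all genes of the comparison, was under 0.05. Log2 fold changes used the default prior count of edgeR's quasi-likelihood fit. A prior count of 2 was used only for log2 CPM, in principal components, the check of the pairs and differences within pairs. SE is the standard error of the log2 fold change. Levels are CPM (counts per M counts of the library, M for mega) as mean ± SD over the libraries of a group. Where 1 group had no reads of a gene, the fold is a lower bound against a floor of 3 counts over that group. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

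The comparisons, tests, gene lists and main alternatives were chosen before the data were examined. The genotypes were compared within each subset, on average over the 5 subsets with equal weights, and for differences of the ITD effect among the 5 subsets and between NC_CD8 and C_CD8 cells. WT subsets were compared as NC_CD8 against C_CD8, NC_CD8 against PDC, and Esamhi against Esamlo. Every genotype result was also computed with a block on the pair of libraries that share a subset and a batch (the pair block), which left 7 residual degrees of freedom and a coefficient of variation of 0.141. WT subset comparisons were also computed with the experiment batch as an additive block, with 11 residual degrees of freedom and a coefficient of variation of 0.174. The pairs come from the batch letters in the labels. They were checked on expression left after subtracting group means: in 12 of 12 pairs the 2 libraries of a pair correlated across genes more closely with each other (r from 0.134 to 0.646) than with any library of the other genotype from another batch of that subset (r up to 0.148). The genes are not independent replicates in this check, and in subsets with 2 batches centring makes the value with the other batch a mirror image.

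The fixed lists were of 2 kinds. Lists of dendritic cell biology covered pDC identity, cDC1 identity, cDC2 identity, monocyte-macrophage-like myeloid genes, DC maturation, MHC class II presentation, MHC class I presentation, interferon-stimulated genes, STAT5 targets, MAPK feedback targets, proliferation, T cell-directed cytokines and ligands, BCL2 family, DC transcription factors and cytokine receptors. Lists used as checks covered early response and handling stress, markers of T cells, B cells, NK cells, neutrophils, erythroid cells, red pulp macrophages, plasma cells, platelets, and progenitors and basophils, and sex-linked genes. Members were counted with p adjusted over all genes and with p adjusted over the list alone. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 260 tests. Camera was repeated with an estimated correlation, with the pair or batch block and with other size factors, and fry was run beside it.

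Genes were named by a rule. For each genotype and WT subset comparison these were the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group. They also had to keep the same sign in every batch pair (genotype comparisons), the same sign in at least 10 of 12 pairs (the average), or no overlap between libraries (WT subset comparisons). The 10 smallest p-values were taken for differences among subsets. Up to 4 members of each list with the smallest p were added in each comparison, and Flt3 in every sample. Applying the rule to the fit with the pair block was decided after seeing the data, as were further alternatives for that fit and fits without batch B. Other genes named, the marker genes of both CD8+ subsets used below and the members counted in lists with the block were singled out after their values were seen.

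Alternatives were DESeq2's RLE size factors, no filter on low counts, DESeq2 in place of edgeR, the pair block, the experiment batch as a block, a fit on the 2 compared groups alone, and each library left out in turn. Where this left 1 library in a group, it was assumed to vary like the other groups. The RLE factors moved the median log2 fold change of any comparison by at most 0.026. The procedure was tested on simulated data, in which 50 genes per fold were changed. Without a block it recovered 92% of genes changed 4-fold and 52% of those changed 2-fold in NC_CD8 cells, and 92% and 28% in PDC. With the pair block it recovered 100% and 88% in NC_CD8 cells. Genes that share long stretches of sequence with another gene were found by comparing all 50-base words of their transcripts.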

Results

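Gene expression was measured by RNA sequencing in dendritic cells sorted from mouse spleen, in 12 WT libraries and 12 ITD libraries. ITD is an internal tandem duplication of Flt3, the receptor of the growth factor that drives dendritic cell development. It is a leukemia-associated activating mutation per the series title. The 5 sorted subsets were PDC (plasmacytoid dendritic cells in the usual reading of this short name), canonical (C_CD8) and non-canonical (NC_CD8) CD8+ cells, and the Esamhi and Esamlo fractions of CD11b+ cells. Each genotype had 3 libraries of C_CD8 and NC_CD8 cells and 2 libraries of PDC, Esamhi and Esamlo cells. Libraries held 11197145 to 22248404 counts. Of the genes in the table, 27542 had at least 1 read. No replicate libraries agreed within counting noise, with a chi-square per degree of freedom from 14.2 to 94.2 between libraries of a group. The first principal component held 38.6% of the variance and the next 18.8%. Subset accounted for a share of 0.994 and 0.964 of their variance. Genotype accounted for 0.000213 and 0.0113 of them. Batch, partly confounded with subset, accounted for 0.589 and 0.0716 of them and for 0.791 of the fifth component, which held 3.52% of the variance.

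**Figure D1:**
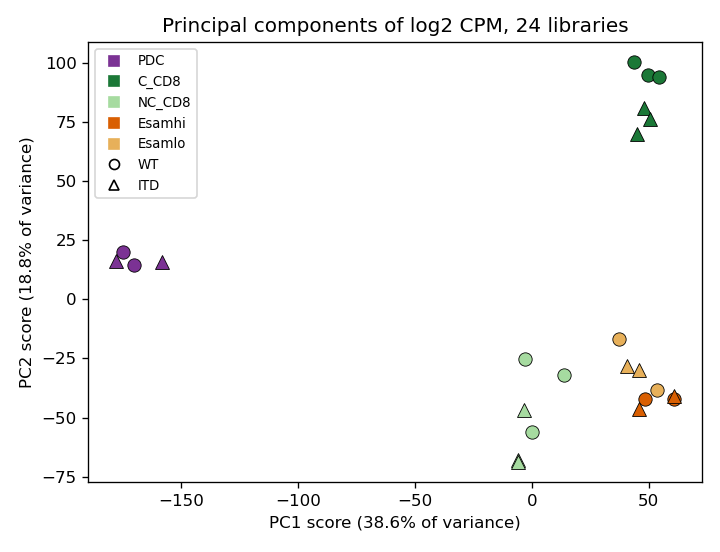
Scores of the 24 libraries on the first and the second principal component of log2 CPM, with axes in log2 units and the share of variance of each component. Colours give the subset, circles WT and triangles ITD libraries, and the libraries group by subset on both axes.

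NC_CD8 and C_CD8 cells of WT mice were compared first. NC_CD8 cells expressed genes of plasmacytoid cells and of CD11b+ dendritic cells at higher levels. Tcf4, a transcription factor required by plasmacytoid cells, was at 474 ± 84.6 CPM (SD, n = 3) against 30.5 ± 3.68 CPM (n = 3). Cd209d, a C-type lectin, was at 258 ± 46.7 against 1.08 ± 0.467 CPM. C_CD8 cells expressed the genes of cross-presenting type 1 dendritic cells (cDC1) at higher levels, with the chemokine receptor Xcr1 at 984 ± 293 CPM against 74 ± 65.8 CPM in NC_CD8 cells. Of 18093 genes tested, 2253 were higher and 2275 lower in NC_CD8 cells.

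Of 20 pDC identity genes, 16 were higher in NC_CD8 cells, with a median log2 difference of 2.99 over the list (camera adjusted p = 6.73e-24). They included Tcf4 (log2 3.96 ± 0.20 SE, adjusted p = 7.48e-10), Zeb2 (4.83 ± 0.36, adjusted p = 6.49e-08), Spib (4.22 ± 0.33, adjusted p = 8.51e-08) and the lectin receptor Siglech (5.30 ± 0.60, adjusted p = 4.42e-06). Of 19 cDC2 identity genes, 13 were higher and 1, Gpr4, was lower (median 3.33, adjusted p = 2.22e-20). Among these, Cd209a differed by 5.66 ± 0.29, Irf4 by 4.69 (adjusted p = 1.49e-06) and Clec10a by 5.09. Of 20 cDC1 identity genes, 19 were lower (median -3.11, adjusted p = 1.18e-16, and adjusted p = 0.066 with an estimated correlation). Among them were Xcr1 (-3.73 ± 0.57), Clec9a (-1.99 ± 0.30), Cadm1 (-2.32) and Irf8 (-2.68). Among 30 DC transcription factors, 16 were higher and 4 lower (adjusted p = 6.24e-09). MHC class I presentation genes were lower in 10 of 16 cases (adjusted p = 4.62e-08, and adjusted p = 0.0559 with an estimated correlation). The peptide transporter Tap1 was at 590 ± 55.2 CPM in C_CD8 and 210 ± 34.1 CPM in NC_CD8 cells. Adjusted over the list alone, 18 transcription factors were higher and 4 lower, and the counts of the other lists of this paragraph did not change.

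The largest differences also included Klra17 (log2 6.79 ± 0.58, 123 against 1.12 CPM), the leukotriene enzyme Alox5 (7.29), Cd209c (6.88; a share of its sequence, 11.6% of 50-base words, occurs in other genes), Dab2 (6.65) and the chemokine receptor Cx3cr1 (6.23, adjusted p = 1.06e-06). Aqp3, Ephb6 and Rab6b had log2 differences of 8.05, 8.01 and 7.79, with at most 2 reads each in the C_CD8 WT libraries. Genes higher in C_CD8 cells included Il12b, a subunit of the cytokine IL-12 (-4.98 ± 0.82; 274 ± 155 against 8.7 CPM) and the signalling feedback gene Socs2 (-2.71, adjusted p = 0.000113). The chemokines Ccl7 (-5.38), Cxcl11 (-4.49), Cxcl9 (-3.62) and Ccl22 (-3.82) were higher in C_CD8 cells as well. DC maturation genes went both ways, with 6 higher and 10 lower of 22 (adjusted p = 0.146). So did interferon-stimulated genes, with 6 higher and 7 lower of 26 (median -0.01, mean 0.28, test direction down, adjusted p = 0.892). Monocyte-macrophage-like genes were higher in 11 and lower in 2 of 20 cases (adjusted p = 0.00669, and adjusted p = 0.317 with an estimated correlation). Proliferation genes were lower in 8 of 30 (adjusted p = 0.000457, and adjusted p = 0.709 with an estimated correlation). MHC class II genes were higher in 6 of 13 (adjusted p = 0.0283, and adjusted p = 0.572 with an estimated correlation). T cell markers were higher in 7 of 15 (adjusted p = 0.00126, and adjusted p = 0.314 with an estimated correlation). NK cell markers were higher in 2 of 14 (adjusted p = 0.0193, and adjusted p = 0.663 with an estimated correlation). Adjusted over the list alone, 12 proliferation genes were lower, 11 monocyte-macrophage-like genes were higher and 4 lower, and 7 interferon-stimulated genes were higher and 8 lower. Progenitor and basophil markers (2 higher and 1 lower of 13, adjusted p = 0.782) and plasma cell markers (2 higher and 1 lower of 9, adjusted p = 0.613) were not called as lists. With the experiment batch as a block the calls were 3718 higher and 3885 lower. Cytokine receptors (adjusted p from 0.0744 to 0.0116) and B cell markers (from 0.121 to 0.0476) became called as higher. Neither held with an estimated correlation as well (adjusted p = 0.0655 and adjusted p = 0.428).

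**Figure D2:**
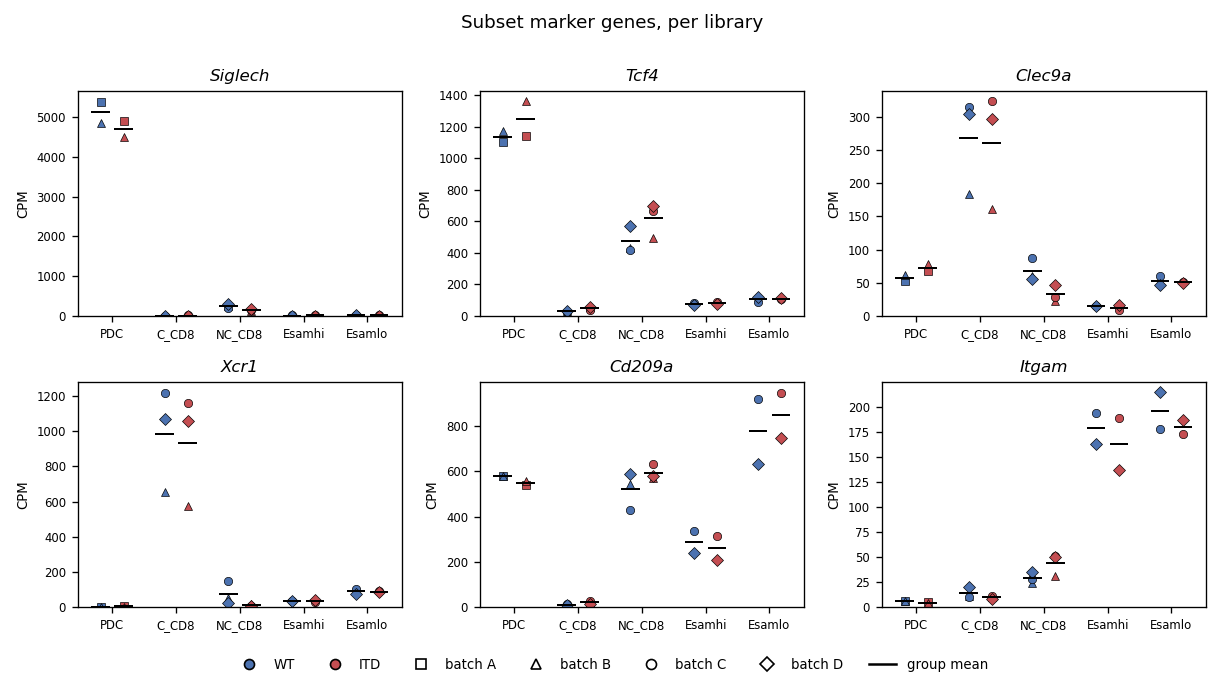
CPM (linear axis) of Siglech, Tcf4, Clec9a, Xcr1, Cd209a and Itgam in each of the 24 libraries by subset and genotype, with blue for WT, red for ITD, marker shape for batch and bars for group means. In NC_CD8 WT cells Siglech averaged 254 CPM, between C_CD8 (6.42 CPM) and PDC (5120 CPM), while Cd209a averaged 520 CPM against 10.3 CPM in C_CD8.

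NC_CD8 cells were set beside PDC in WT mice because both expressed plasmacytoid genes. NC_CD8 cells had far lower levels of most plasmacytoid genes than PDC and higher levels of genes of conventional dendritic cells. The conventional dendritic cell transcription factor Zbtb46 was at 363 ± 9.58 CPM (SD, n = 3) in NC_CD8 cells and at 3.2 ± 0.13 CPM (n = 2) in PDC. H2-Ob, a regulator of peptide loading on MHC class II, was at 634 ± 88 against 14.5 ± 0.216 CPM. Cox6a2, which marks plasmacytoid cells, was at 2.17 ± 0.544 against 295 ± 60.4 CPM. Of 18093 genes, 2474 were higher and 2303 lower in NC_CD8 cells.

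Of 20 pDC identity genes, 17 were lower in NC_CD8 cells (median log2 -3.26, camera adjusted p = 2.48e-19). Cox6a2 (-7.07 ± 0.44), Ccr9 (-4.50 ± 0.40), Siglech (-4.33 ± 0.59), Bst2 (-3.12 ± 0.23) and Spib (-3.22) were among them, with a smaller difference for Tcf4 (-1.26 ± 0.19, adjusted p = 7.76e-05). Of 13 MHC class II genes, 11 were higher, and 13 with p adjusted over the list alone (median 1.60, adjusted p = 1.52e-17), including H2-Ob (5.45 ± 0.19, adjusted p = 9.63e-13) and H2-Eb1 (2.36). Of 36 T cell-directed cytokines and ligands, 25 were higher and 4 lower (median 3.52, adjusted p = 3.73e-10), including Il1b (8.37), Cxcl16 (5.47), Cd80 (6.95) and Cd86 (4.61). Of 22 DC maturation genes, 18 were higher and 1, Cd200, was lower (median 3.53, adjusted p = 3.82e-12, and adjusted p = 0.0563 with an estimated correlation), including Cd40 (3.42 ± 0.19) and Fscn1, an actin-bundling protein of mature dendritic cells (5.79 ± 0.46). cDC1 genes were higher in 14 and lower in 2 of 20 cases (adjusted p = 1.19e-07, and adjusted p = 0.261 with an estimated correlation), with Batf3 at 5.99. cDC2 genes were higher in 10 and lower in 3 of 19 (adjusted p = 5.39e-05, and adjusted p = 0.137 with an estimated correlation). DC transcription factors were higher in 16 and lower in 4 of 30 (adjusted p = 0.000533, and adjusted p = 0.132 with an estimated correlation). Interferon-stimulated genes were lower in 12 and higher in 4 of 26 (adjusted p = 0.00211, and adjusted p = 0.572 with an estimated correlation), with Irf7 at -3.13 ± 0.23. Monocyte-macrophage-like genes were higher in 11 and lower in 2 of 20 (adjusted p = 0.00356, and adjusted p = 0.249 with an estimated correlation). Adjusted over the list alone, 26 T cell-directed genes were higher and 6 lower. So were 19 and 1 DC maturation, 15 and 2 cDC1, 16 and 5 transcription factor, 4 and 13 interferon-stimulated, and 14 and 2 monocyte-macrophage-like genes.

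Several genes had no reads in PDC WT libraries and were at least 332-fold (2900026A02Rik), 224-fold (Ptgir), 157-fold (Dcstamp) and 138-fold (Egr3) higher in NC_CD8 cells. Zfp366 was at 59.5 against 0.0468 CPM (log2 10.11). In the other direction the kallikrein Klk1b21 was at least 335-fold lower in NC_CD8 cells (29.1% of its 50-base words occur in other genes). Dcn, Col3a1 and Serping1, genes of fibroblasts, were at least 702-fold, 450-fold and 286-fold lower. Dcn, however, was at 37.6 ± 52.6 CPM in PDC WT, with 74.8 CPM in the library of batch B, and these 3 calls were lost without that library (PDC WT replicate 2). Those of Dcn and Col3a1 were also lost without any 1 of the NC_CD8 WT libraries. Plasma cell markers were lower in 5 and higher in 1 of 9 cases (adjusted p = 0.000902, and adjusted p = 0.0561 with an estimated correlation), with Xbp1 at -2.99 and Sdc1 at -6.30. Markers of NK cells (8 of 14 higher, adjusted p = 0.0131; with the batch block adjusted p = 0.134) and of red pulp macrophages (9 of 14 higher, adjusted p = 0.00231; with the block 0.313) moved with NC_CD8 cells. Neither held with an estimated correlation (adjusted p = 0.619 and adjusted p = 0.636). PDC and NC_CD8 libraries share batch B alone. With the batch block 4124 genes were higher and 3746 lower. MHC class I (adjusted p from 0.0193 to 0.0783), proliferation (from 0.0227 to 0.0732) and early response and handling stress genes (from 0.0215 to 0.0872) were then no longer called. STAT5 targets (from 0.0518 to 3.96e-05), the BCL2 family (from 0.0635 to 0.0176) and sex-linked genes (from 0.548 to 1.07e-13, from 0 of 5 genes called to 4 higher and 1 lower) became called as higher. With an estimated correlation as well, STAT5 targets (adjusted p = 0.0259) and sex-linked genes (adjusted p = 0.0162) held and the BCL2 family did not (adjusted p = 0.118). Cytokine receptors were higher in 10 and lower in 6 of 22 cases (adjusted p = 0.662).

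Esamhi and Esamlo cells, the fractions of CD11b+ cells by the adhesion molecule Esam, differed less. Esamlo cells had higher levels of genes shared with monocytes: the lectin Clec12a was at 199 CPM in Esamlo and 42.6 CPM in Esamhi cells (n = 2 each, log2 -2.22 ± 0.19, adjusted p = 2.08e-05). The chemokine receptor Ccr2 was at 362 against 65.2 CPM (-2.47, adjusted p = 0.0207). Esamhi cells had higher levels of Dtx1, a target of Notch signalling (291 against 71.1 CPM; 2.03 ± 0.42, adjusted p = 0.0318), and of Socs2 (2.37 ± 0.50, adjusted p = 0.0361). Esam itself differed by 2.79 ± 0.67 and did not pass (adjusted p = 0.0698). In WT, 24 genes were higher and 95 lower in Esamhi cells.

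Of 20 monocyte-macrophage-like genes, 3 were lower in Esamhi cells, and 7 with p adjusted over the list alone (median -1.37, camera adjusted p = 1.34e-13): Clec12a, Ccr2 and Fcgr3 (10.2 against 69.5 CPM; 9.58% of its 50-base words are shared, mainly with Fcgr2b). Of 20 cDC1 genes, 3 were lower, and 9 over the list alone (median -1.41, adjusted p = 4.63e-11, and adjusted p = 0.181 with an estimated correlation): Clec9a (-1.80), Cd8a (-1.58) and Cadm1 (-1.32). Of 22 DC maturation genes, only Socs2 was higher over all genes, and 6 over the list alone (adjusted p = 5.82e-06, and adjusted p = 0.218 with an estimated correlation). cDC2 genes were higher in 1 and lower in 3 of 19 cases (adjusted p = 0.939): the lectins Clec10a (-3.18 ± 0.45, 9.23 against 84.1 CPM), Mgl2 (-3.08 ± 0.47) and Cd209a (-1.44, adjusted p = 0.0268) were lower and Dtx1 higher. Among the largest differences, Ptgir (-3.81), Cd226 (-2.94), Tppp3 (-2.93), Mcub (-2.81), Cysltr1 (-2.70), Pdlim1 (-2.55) and Cd209c (-2.49) were lower in Esamhi cells. Ppp1r14a (1.47), St14 (1.39), Galnt12 (1.39), Clstn1 (1.34) and Ddb2 (1.23) were higher. NK cell markers were lower as a list (adjusted p = 0.0104, and adjusted p = 0.61 with an estimated correlation). Proliferation genes were higher (adjusted p = 0.0124, and adjusted p = 0.821 with an estimated correlation). The lists had 0 of 14 and 0 of 30 genes called by edgeR. The pDC list was lower (adjusted p = 0.035, and adjusted p = 0.551 with an estimated correlation) and was not called with the batch block (adjusted p = 0.0572). With the batch block 475 genes were higher and 676 lower. The count of 119 dropped to 11 without Esamhi WT replicate 1, to 4 without Esamhi WT replicate 2, to 12 without Esamlo WT replicate 1 and to 11 in a fit on these 2 groups alone. Of the named genes, Clec12a kept its call whichever library was left out.

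The ITD effect was averaged over the 5 subsets (12 pairs of 4 batches, perhaps dependent). Socs2, a STAT5-induced feedback inhibitor, rose by log2 2.39 ± 0.21 (SE, adjusted p = 1.45e-05, higher in 12 of 12 pairs). Cdh2 (N-cadherin) rose by 7.09 ± 0.90 (adjusted p = 0.00214, 12 of 12 pairs). Its reads ran from 0 to 12 in WT groups and from 6 (PDC) to 766 (C_CD8) in ITD groups. With 0 WT reads in PDC and NC_CD8 the fold is uncertain. Fscn1 rose by 1.32 ± 0.16 (adjusted p = 0.000712, 12 of 12) and Cd40 by 0.59 ± 0.07 (adjusted p = 0.000727, 12 of 12). Apoe fell by 0.92 ± 0.13 (adjusted p = 0.00293; lower in 12 of 12 pairs). In all 60 genes rose and 5 fell, and 1236 (813 rose and 423 fell) were called with the pair block, the 65 included. Without the pairs Esamhi D, PDC B and Esamhi C that count was 549, 605 and 641.

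Flt3 itself (ENSMUSG00000042817, mm10 chromosome 5, 147330741 to 147400489, minus strand) was lower in ITD in 12 of 12 pairs. Its level was 303 ± 29 CPM in WT and 265 ± 21.2 in ITD PDC, 539 ± 87.5 and 365 ± 43 in C_CD8, and 891 ± 70.3 and 730 ± 29 in NC_CD8 cells. It was 439 ± 3.54 and 395 ± 0.523 CPM in Esamhi and 538 ± 21 and 433 ± 18.3 in Esamlo cells. On average it differed by log2 -0.30 ± 0.06, which did not pass without the block (adjusted p = 0.0504) and passed with it (adjusted p = 0.00139).

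Of 22 DC maturation genes, 3 rose (Socs2, Fscn1 and Cd40), 10 with p adjusted over the list alone and 13 with the block (median 0.36, camera adjusted p = 1.91e-18). The 13 included Ccr7 (0.69, adjusted p = 0.000213), Relb (0.37, adjusted p = 0.000129) and Icosl (0.48, adjusted p = 0.000509). Il12b (1.08, adjusted p = 0.00711) rose too, mainly in PDC (4 WT, 72 ITD reads). Of 26 interferon-stimulated genes, 2 rose, 17 over the list alone and 16 with the block (median 0.50, adjusted p = 1.53e-23; with block and estimated correlation together 0.0614). The 2 were Ifi44 (1.74 ± 0.32, adjusted p = 0.0202; 11 of 12 pairs) and Ifi203 (0.77 ± 0.11, adjusted p = 0.00293; 12 of 12). With the block they included Ifit1 (1.36) and Oas1a (1.31). Of 13 MHC class II genes, 1 rose, the lysosomal reductase Ifi30 (0.26 ± 0.05, adjusted p = 0.0422), 5 over the list alone and 9 with the block (adjusted p = 7.01e-06, and adjusted p = 0.166 with an estimated correlation). MHC class I genes rose in 0 of 16 cases, 4 over the list alone and 3 with the block (adjusted p = 0.0059, and adjusted p = 0.314 with an estimated correlation). The last were H2-K1, H2-D1 and Nlrc5 (0.51, adjusted p = 0.000213). Of 18 STAT5 targets, Socs2 alone rose, with 2 up and 1 down over the list alone (adjusted p = 0.000831, and adjusted p = 0.0949 with an estimated correlation). With the block 5 rose and 1, Ccnd1, fell. T cell-directed cytokines and ligands rose in 1 of 36 cases, 6 over the list alone and 9 with the block (adjusted p = 0.0048, and adjusted p = 0.222 with an estimated correlation). Among them with the block were Tnfsf4, the ligand of OX40 (1.96, adjusted p = 0.00204), and Ccl5 (0.73). DC transcription factors were higher as a list (adjusted p = 0.0242, and adjusted p = 0.342 with an estimated correlation), with 0 of 30 called and 9 up and 1 down with the block, including Spib (0.59, adjusted p = 1.02e-05; 0.0937 without it).

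Other genes that rose were Cp, the copper-carrying ferroxidase (2.28 ± 0.42, adjusted p = 0.0192; 12 of 12 pairs), the IL-36 receptor Il1rl2 (1.89 ± 0.36, adjusted p = 0.021; 11 of 12) and Plxdc2 (1.70 ± 0.18, adjusted p = 0.00018; 10 of 12). So did the VEGF receptor Kdr (1.45 ± 0.25, adjusted p = 0.0106; 12 of 12), Myo1e (1.40) and Prph (1.90). Gm9847 rose by 2.29 ± 0.20, but 76% of its 50-base words are shared, mainly with Socs2, so its reads cannot be assigned with certainty. Besides Apoe, the genes that fell were the B lymphoid kinase Blk (-1.10 ± 0.21, adjusted p = 0.0227; higher in 1 of 12 pairs) and the NADPH oxidase subunit Ncf4 (-0.51 ± 0.08, adjusted p = 0.00454; higher in 2 of 12). Tnni2 (-0.48, adjusted p = 0.0486; 0 of 12) and the inhibitory receptor Btla (-0.41 ± 0.08, adjusted p = 0.0307; 2 of 12) fell too. Identity lists moved little: cDC1 genes were lower as a list (median -0.27, adjusted p = 0.000662, and adjusted p = 0.551 with an estimated correlation; 0 of 20 called, 3 over the list alone, 4 with the block). cDC2 genes (median -0.11, mean 0.01, test direction up, adjusted p = 0.333) and pDC genes (adjusted p = 0.444) were not called. Proliferation genes were lower (adjusted p = 0.000472, and adjusted p = 0.709 with an estimated correlation), with 0 of 30 called and 2 with the block. Monocyte-macrophage-like genes were called lower without the block (adjusted p = 0.0373, and adjusted p = 0.489 with an estimated correlation) and not with it (0.205).

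Markers of some cells other than dendritic cells were lower in ITD libraries. NK cell markers had a median of -1.39 on average (adjusted p = 1.58e-07, and adjusted p = 0.222 with an estimated correlation). Of these, 0 of 14 were called over all genes, 5 were lower over the list alone, and with the block 7 fell, such as the granzyme Gzma (-3.06, adjusted p = 0.00419), and Klrd1 rose (0.25, adjusted p = 0.0191). B cell markers (1 of 14, Blk, adjusted p = 0.00499, and adjusted p = 0.572 with an estimated correlation), erythroid markers (0 of 13, adjusted p = 0.0321, and adjusted p = 0.61 with an estimated correlation) and red pulp macrophage markers (0 of 14, adjusted p = 0.00643, and adjusted p = 0.685 with an estimated correlation) were lower too. Markers of T cells (adjusted p = 0.269), platelets (0.155), neutrophils (0.511), plasma cells (0.277) and progenitors and basophils (0.569, test direction up) were not called.

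The 10 camera calls that held with an estimated correlation were DC maturation (adjusted p = 0.0216) and interferon-stimulated genes (0.0292) on average, cDC1 identity in NC_CD8 ITD cells (0.0368), pDC (0.00695), cDC2 (0.00695) and transcription factor genes (0.0262) between the CD8+ subsets. The others were pDC (0.0108), MHC class II (0.0173) and T cell-directed genes (0.0165) between NC_CD8 cells and PDC, and monocyte-macrophage-like genes between the CD11b+ subsets (0.0165). With block and estimated correlation together, an alternative chosen after the data were seen, 31 of 260 list tests were called. DC maturation genes were higher on average (adjusted p = 0.0162), in PDC (0.0162), C_CD8 (0.02), NC_CD8 (0.0371), Esamhi (0.0162) and Esamlo cells (0.02). STAT5 targets were higher on average (adjusted p = 0.0371), in C_CD8 (0.0328) and in NC_CD8 cells (0.0258), and transcription factors on average (0.0481) and in C_CD8 cells (0.0162). In C_CD8 cells pDC genes (adjusted p = 0.0258) and cytokine receptors (0.0348) were higher too, while MAPK feedback targets were lower in PDC (0.0259) and B cell markers in NC_CD8 cells (0.0259). Between the CD8+ subsets the ITD effect was lower in NC_CD8 cells for pDC genes (adjusted p = 0.0259) and for markers of T cells (0.0258) and B cells (0.0437). The count of 65 dropped to 40 without Esamhi WT replicate 1, to 41 without Esamhi WT replicate 2, to 40 without Esamhi ITD replicate 2 and to 38 without Esamlo ITD replicate 2, and it was 121 without batch B. Socs2, Gm9847, Plxdc2, Kdr, Fscn1, Cd40, Ifi203, Apoe and Ncf4 kept their calls whichever library was left out, and Cdh2 did in all but the fit without PDC ITD replicate 1.

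**Figure D3:**
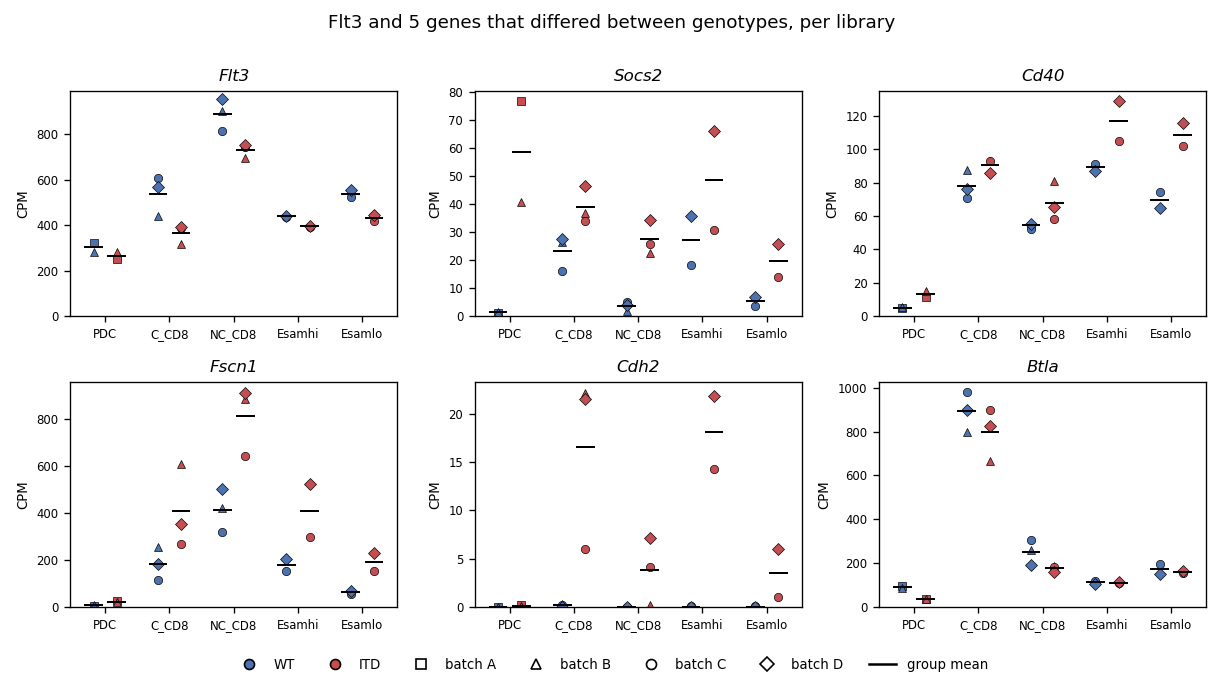
CPM (linear axis) of Flt3, Socs2, Cd40, Fscn1, Cdh2 and Btla in each of the 24 libraries by subset, with blue for WT, red for ITD, marker shape for batch and bars for group means. Flt3 is lower and Socs2, Cd40, Fscn1 and Cdh2 are higher in ITD in 12 of 12 pairs, and Btla differs by the largest ratio in PDC (90.6 against 37.9 CPM).

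In PDC, the comparison asked how ITD acts on plasmacytoid cells. Socs2 rose from 1.29 ± 0.258 CPM (SD, n = 2) in WT to 58.6 ± 25.2 CPM (n = 2) in ITD, a log2 change of 5.50 ± 0.59 (SE; adjusted p = 0.000305). Cd40 rose from 5.08 ± 0.33 to 13 ± 2.57 CPM (1.36 ± 0.19, adjusted p = 0.00423), and the inhibitory receptor Btla fell from 90.6 ± 5.11 to 37.9 ± 1.03 CPM (-1.26 ± 0.20, adjusted p = 0.0181). In all, 9 genes rose and 2 fell, and 21 rose and 24 fell with the pair block, which kept 9 of the 11. Without the pair of batch A or B the latter count was 16 or 8.

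The other named rises were 1700025G04Rik (1.90 ± 0.23, adjusted p = 0.00102), Chn2 (1.85, adjusted p = 0.00423), the Fc receptor-like gene Fcrl1 (2.47, adjusted p = 0.0139), the junction protein Jup (1.77 ± 0.29, 7.16 to 24.4 CPM) and Gm9847 (5.12 ± 0.55, reads shared with Socs2). Sspo (4.48, adjusted p = 0.0328) and Pvt1 (3.23, adjusted p = 0.048) were not called with the block (adjusted p = 0.195 and adjusted p = 0.136). With the block Fscn1 rose by 1.66 ± 0.15 (7.5 to 23.5 CPM; adjusted p = 0.000625, 0.399 without it). So did Lrp1 (2.92 ± 0.36, adjusted p = 0.0056), the guanylate-binding proteins Gbp7 (1.97 ± 0.28; 12.7% of its 50-base words shared) and Gbp2b (1.38), the RNA sensor Ifih1 (1.07, adjusted p = 0.021), Ncaph (1.73) and the mitotic kinase Aurkb (1.51, adjusted p = 0.0348). Dusp6, a phosphatase that limits MAPK signalling, fell from 42.7 ± 4.11 to 13.2 ± 1.16 CPM with the block (-1.69, adjusted p = 0.00592; adjusted p = 1 without it), as did Bcl6 (-0.57) and Apoe (-0.86). The pancreatic protease Ctrc fell (-7.45 ± 1.21, adjusted p = 0.0181; 17.7% of its 50-base words shared with Cela2a). With the block so did further genes of pancreatic acinar cells, such as Pnlip (-10.70), Cpb1 (-7.40) and Reg1 (-7.39). Summed over 20 acinar genes, PDC WT libraries had 139 and 890 CPM and PDC ITD libraries 1.06 and 10.4 CPM.

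Among the lists, 2 of 22 DC maturation genes rose, and 3 over the list alone (median 0.22, adjusted p = 2.78e-12, and adjusted p = 0.0559 with an estimated correlation). Interferon-stimulated genes were higher (median 0.58, adjusted p = 3.85e-12, and adjusted p = 0.102 with an estimated correlation), with 0 of 26 called and 1 over the list alone. Proliferation genes were higher (median 0.74, adjusted p = 5.83e-10, and adjusted p = 0.427 with an estimated correlation), with 0 of 30 called. T cell-directed genes (1 of 36, Cd40; adjusted p = 4.75e-05, and adjusted p = 0.0836 with an estimated correlation) and MHC class II genes (adjusted p = 0.00203, and adjusted p = 0.342 with an estimated correlation) were higher. MAPK feedback targets (median -0.55, adjusted p = 0.00669, and adjusted p = 0.0735 with an estimated correlation) and monocyte-macrophage-like genes (adjusted p = 0.0373, and adjusted p = 0.489 with an estimated correlation) were lower. The pDC identity genes were not called (adjusted p = 0.755), and neither were STAT5 targets (adjusted p = 0.0744) with Socs2 as the 1 gene called. cDC1 genes were higher (adjusted p = 0.0273) and neutrophil markers lower (adjusted p = 0.0227), which the block ended (0.199 and 0.0921). Neither held with an estimated correlation (adjusted p = 0.711 and adjusted p = 0.619). Early response and handling stress genes were lower (adjusted p = 0.0395, and adjusted p = 0.61 with an estimated correlation), with 0 of 20 called. The count of 11 dropped to 4 without PDC WT replicate 2, to 6 without PDC ITD replicate 1, to 7 without PDC ITD replicate 2 and to 0 in a fit on these 2 groups alone. Socs2, Gm9847 and 1700025G04Rik kept their calls whichever library was left out.

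In C_CD8 cells, the comparison asked what ITD does to canonical CD8+ cells. The lectin Cd209d rose from 1.08 ± 0.467 CPM (SD, n = 3) to 5.24 ± 1.3 CPM (n = 3), a log2 change of 2.26 ± 0.34 (SE; adjusted p = 0.0286). In all, 3 genes rose and 0 fell in edgeR, with 787 genes at an unadjusted p under 0.05 and 98 called by DESeq2. With the pair block 215 rose and 8 fell, with fewer called without any 1 pair (86 without that of batch B to 143 without that of D). Among the 223, Spib rose by 1.73 (6.72 ± 2.42 to 22.1 ± 6.79 CPM; adjusted p = 5.62e-06, 0.0695 without the block), Cdh2 by 6.22 ± 0.57 (adjusted p = 0.00136), Fscn1 by 1.14 (adjusted p = 0.000286) and Tnfsf4 by 3.37 (adjusted p = 0.00225). Flt3 fell by 0.56 ± 0.08 (adjusted p = 0.00438, 0.169 without it).

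Several genes that rose with the block were at higher levels in NC_CD8 than in C_CD8 cells. These were Tcf4 (0.74, adjusted p = 0.00472; 30.5 to 51.2 CPM), Zeb2 (1.33, adjusted p = 0.0267), Atp1b1 (1.61), Cd209a (0.96, adjusted p = 0.00959), Sirpa (1.05, adjusted p = 0.0383), Ccr2 (1.32, adjusted p = 0.00725), S100a4 (1.86, adjusted p = 0.000286), Il2rg (1.05), Il7r (1.62), Tcf7 (1.35) and Klrd1 (1.16). As lists, pDC identity (median 0.65, adjusted p = 3.38e-07, and adjusted p = 0.0949 with an estimated correlation; 0 of 20 called, 4 over the list alone, 6 with the block), cDC2 identity (adjusted p = 0.00018, and adjusted p = 0.156 with an estimated correlation; 2 of 19 over the list alone) and DC transcription factors (adjusted p = 0.000101, and adjusted p = 0.101 with an estimated correlation; 4 of 30 over the list alone) were higher. A set of 26 genes marked for NC_CD8 cells, picked on WT and ITD levels in C_CD8 cells together, lay at 6.23%, 3.4% and 3.51% of their NC_CD8 WT level in C_CD8 ITD libraries of batches B, C and D, and at 2.45%, 1.68% and 2.44% in the C_CD8 WT libraries. Interferon-stimulated genes (adjusted p = 4.06e-15, and adjusted p = 0.0803 with an estimated correlation; 6 of 26 over the list alone) and DC maturation genes (adjusted p = 3.95e-05, and adjusted p = 0.234 with an estimated correlation; 1 of 22 over the list alone, 5 with the block) were higher too, with Relb (0.73) and Icosl (0.76) among those called with the block. STAT5 targets (adjusted p = 0.0199, and adjusted p = 0.222 with an estimated correlation), cytokine receptors (adjusted p = 0.0496, and adjusted p = 0.222 with an estimated correlation) and T cell-directed genes (adjusted p = 0.0464, and adjusted p = 0.406 with an estimated correlation) were higher and proliferation genes lower (adjusted p = 0.000902, and adjusted p = 0.728 with an estimated correlation).

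Further rises with the block were Il9r (3.44, adjusted p = 0.0188), Chst7 (2.65), Igsf3 (2.57, adjusted p = 0.000882), Efnb2 (2.57), the integrin Itgb3 (2.40, adjusted p = 0.000364), Ttn (2.36), Dscam (2.30) and Ifi203 (1.11). Further falls were the Hedgehog pathway receptor Smo (-0.86, adjusted p = 0.043), Car9 (-0.81), Gmds (-0.79), L3mbtl3 (-0.72), Cd38 (-0.53) and Ranbp1 (-0.35). The block also called monocyte-macrophage-like genes (adjusted p from 0.121 to 0.00526) and T cell markers (from 0.121 to 0.00522) higher and red pulp macrophage markers (from 0.296 to 0.0363) lower. With an estimated correlation as well they were not called (adjusted p = 0.488, adjusted p = 0.228 and adjusted p = 0.648). The count of 3 was 6 without C_CD8 WT replicate 1, 0 without WT replicate 2, WT replicate 3 or ITD replicate 3, 1 without ITD replicate 1 and 23 without ITD replicate 2. Cd209d was not called without WT replicates 2 or 3 or ITD replicates 1 or 3. It was 0 without batch B and 0 in a fit on these 2 groups alone.

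In NC_CD8 cells, the comparison asked the same of non-canonical CD8+ cells. Socs2 rose from 3.55 ± 1.53 CPM (SD, n = 3) to 27.4 ± 6.09 CPM (n = 3), a log2 change of 2.95 ± 0.42 (SE; adjusted p = 0.0065). Ccn3, a matricellular protein, had no reads in WT and was at 11.9 ± 5.69 CPM in ITD, at least 221-fold higher (adjusted p = 0.0184). Genes of cDC1 fell: Xcr1 from 74 ± 65.8 to 10.2 ± 4.5 CPM (-2.87 ± 0.56, adjusted p = 0.0335) and the scavenger receptor Cd36 from 48.8 ± 39.6 to 6.62 ± 2.49 CPM (-2.89 ± 0.50, adjusted p = 0.0143). Apoe fell from 190 ± 22.7 to 66.1 ± 17.7 CPM (-1.52 ± 0.26, adjusted p = 0.0143). In all, 19 genes rose and 37 fell, and 431 rose and 435 fell with the pair block, the 56 included. Without the pair of batch C or D the count of 866 was 244 or 490.

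Of 20 cDC1 identity genes, 5 fell, 13 over the list alone and 16 with the block (median -2.07, camera adjusted p = 8.03e-27; with block and estimated correlation together 0.0614). The 5 were Xcr1, Cd36, the RNA sensor Tlr3 (-3.61 ± 0.72, adjusted p = 0.0358), Gcsam (-3.35 ± 0.62, adjusted p = 0.021) and Ifi205 (-2.30 ± 0.42, adjusted p = 0.0184). With the block Clec9a (-1.09, adjusted p = 0.0107) and Irf8 (-1.59, adjusted p = 0.00861) fell as well. WT libraries of NC_CD8 cells varied in these genes: a set of 6 genes marked for C_CD8 cells lay at 10.7%, 17.1% and 2.73% of their C_CD8 WT level in NC_CD8 WT libraries of batches B, C and D, and at 1.77%, 1.78% and 1.56% in the ITD libraries. The median difference of the cDC1 list was -1.80, -2.58 and -0.71 in these batches. Markers of some cells other than dendritic cells were lower as well, with medians of -2.25 for NK cells (adjusted p = 0.000179, and adjusted p = 0.407 with an estimated correlation), -1.62 for T cells (adjusted p = 4.07e-05, and adjusted p = 0.222 with an estimated correlation) and -0.55 for B cells (adjusted p = 0.000103, and adjusted p = 0.347 with an estimated correlation). Erythroid (adjusted p = 0.00222, and adjusted p = 0.427 with an estimated correlation) and red pulp macrophage markers (adjusted p = 0.000567, and adjusted p = 0.6 with an estimated correlation) were lower too. Neutrophil (adjusted p = 0.675), plasma cell (0.389), platelet (0.438) and progenitor and basophil markers (0.216, test direction up) were not called. With the block the members that fell included Gzma (-4.90, adjusted p = 0.012), Nkg7 (-2.34), Cd6 (-1.54), Cd8b1 (-1.05), Hbb-bs (-2.98) and Vcam1 (-1.98; 121 ± 149 against 21.8 ± 16.4 CPM). Proliferation genes were lower (median -0.91, adjusted p = 8.23e-16, and adjusted p = 0.261 with an estimated correlation), with 0 of 30 called, 4 over the list alone and 11 with the block, among them Mcm6 (-0.92, adjusted p = 0.000978) and Rrm2 (-1.61, adjusted p = 0.0091).

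Lists that were higher in NC_CD8 ITD cells were DC maturation (adjusted p = 0.0024, and adjusted p = 0.409 with an estimated correlation; 1 of 22 rose, 6 rose and 1 fell with the block), MHC class II (adjusted p = 0.00082, and adjusted p = 0.284 with an estimated correlation; 0 of 13, 3 over the list alone), interferon-stimulated genes (adjusted p = 5.63e-05, and adjusted p = 0.375 with an estimated correlation; 1 of 26, Ifi203) and STAT5 targets (adjusted p = 0.0135, and adjusted p = 0.218 with an estimated correlation). Among STAT5 targets Socs2 rose and the cyclin Ccnd1 fell (-1.07 ± 0.22, adjusted p = 0.0496), and with the block the kinase Pim2 rose (1.02, adjusted p = 0.000684). Named rises were Repin1 (2.32 ± 0.36, 6.95 to 34.9 CPM, adjusted p = 0.0103), Gbp7 (2.21 ± 0.41), Olfm1 (1.86, 34.8 to 126 CPM), the calcium channel subunit Cacnb2 (1.74), Gbp2b (1.47) and Ifi203 (1.44 ± 0.23, adjusted p = 0.0103; 12.2% of its 50-base words shared, and Ifi203-ps, 26.3% shared, rose by 1.60). Gm9847 rose by 3.24. With the block they included Apod (3.01, adjusted p = 0.00307), Cp (2.43; 29.9 ± 5.71 to 160 ± 11.6 CPM), Mir155hg (2.38, adjusted p = 0.000827), Fscn1 (0.98, adjusted p = 0.000581, 0.318 without the block), Mgl2 (1.28), Clec10a (1.03) and Cd74 (0.35). Named falls were Ttc39a (-3.86 ± 0.56, adjusted p = 0.00658), Fam149a (-3.51), Hk3 (-3.41), Gpr141b (-3.12), Treml4 (-2.97, adjusted p = 0.0133), Serpinb2 (-2.95), Blk (-2.51 ± 0.44, adjusted p = 0.0175) and a gene ID with no symbol in the reference (-3.13). With the block Gramd2 (-6.06), the lectin Cd207 (-3.56, adjusted p = 0.00042), Dkk3 (-3.96) and Dusp6 (-1.18) fell as well.

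Plasmacytoid genes had a median of 0.12, a mean of -0.22 and a test direction of down in NC_CD8 cells (adjusted p = 0.339), with 4 up and 6 down with the block. Transcription factors had a median of 0.15 and a mean of -0.02 (adjusted p = 0.372), and were called higher with the block (adjusted p = 0.0496, and adjusted p = 0.281 with an estimated correlation as well). cDC2 (adjusted p = 0.467) and BCL2 family genes (adjusted p = 0.508) were not called, and early response genes were called higher with the block alone (adjusted p from 0.0835 to 0.0341, and adjusted p = 0.627 with an estimated correlation as well). The count of 56 was 13 without NC_CD8 WT replicate 2, 83 without WT replicate 3, 36 without ITD replicate 1, 4 without ITD replicate 2, 9 without ITD replicate 3, 3 in a fit on these 2 groups alone (0 of the 56 among them) and 121 without batch B. Socs2 and Gm9847 kept their calls whichever library was left out, and Repin1 did in all but the fit without ITD replicate 2. Xcr1, Tlr3, Gcsam and Ifi205 lost theirs without WT replicate 2 or any ITD library, as Cd36 and Apoe did without WT replicate 2 or ITD replicates 2 or 3.

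In Esamhi cells, the comparison asked how ITD acts on this CD11b+ fraction, and the genes named here were called in the fit with the pair block. Cdh2 rose by log2 8.90 ± 0.89 (SE; adjusted p = 0.0171), from 0.0286 ± 0.0405 CPM (SD, n = 2; 1 read in WT) to 18.1 ± 5.41 CPM (n = 2). Kdr rose by 2.26 ± 0.27 (1.76 ± 0.552 to 8.39 ± 1.07 CPM, adjusted p = 0.0149) and Fscn1 by 1.17 ± 0.12 (178 ± 36.3 to 410 ± 160 CPM, adjusted p = 0.00672). The others were Repin1 (1.41), the MHC class I regulator Nlrc5 (0.88, adjusted p = 0.0261), Tmem123 (0.85, adjusted p = 0.00548), the caspase Casp6 (0.63) and Gtf2a1 (0.62). Without the block edgeR called 0 genes, with 303 at an unadjusted p under 0.05, DESeq2 called 2 and the fit with the batch block 1. With the block 8 rose and 1 fell, and 0 were called when either pair was left out. DC maturation genes were higher as a list (median 0.45, camera adjusted p = 2.21e-08, and adjusted p = 0.111 with an estimated correlation). So were interferon-stimulated genes (adjusted p = 1.09e-06, and adjusted p = 0.259 with an estimated correlation; 1 of 26 over the list alone) and MHC class I genes (adjusted p = 0.000914, and adjusted p = 0.231 with an estimated correlation). MHC class II genes were called higher with the block alone (adjusted p from 0.214 to 0.04, and adjusted p = 0.555 with an estimated correlation as well). MAPK feedback targets were lower without it (adjusted p = 0.0379, and adjusted p = 0.161 with an estimated correlation) and not with it (0.103). NK cell markers had a median of -2.10 (adjusted p = 1.23e-06, and adjusted p = 0.234 with an estimated correlation).

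In Esamlo cells, the comparison asked the same. Plxdc2 rose from 4.51 ± 2.2 CPM (SD, n = 2) to 30.1 ± 0.681 CPM (n = 2), a log2 change of 2.73 ± 0.40 (SE; adjusted p = 0.04). It was the 1 gene called, with 643 genes at an unadjusted p under 0.05 and 2 called by DESeq2. With the pair block 7 genes rose and 2 fell, against 3 called without the pair of batch D and 127 without that of batch C. Fscn1 rose by 1.60 ± 0.13 (62.5 ± 8.52 to 192 ± 53.5 CPM, adjusted p = 0.000595), Socs2 by 1.93 ± 0.28 (adjusted p = 0.0453), Slc4a8 by 1.39, Dapk1 by 1.13, Spib by 0.67 and Tmem123 by 0.56. Apoe fell from 239 ± 35.7 to 98.7 ± 4.2 CPM (-1.27 ± 0.13, adjusted p = 0.00286), and the lymphoid transcription factor Ikzf3 fell by 1.85 (adjusted p = 0.0394). Lists that were higher were DC maturation (median 0.53, camera adjusted p = 1.64e-07, and adjusted p = 0.14 with an estimated correlation; 0 of 22, 4 over the list alone), interferon-stimulated genes (median 0.58, adjusted p = 1.21e-07, and adjusted p = 0.23 with an estimated correlation), MHC class II (adjusted p = 0.000413, and adjusted p = 0.259 with an estimated correlation) and MHC class I (adjusted p = 0.00156, and adjusted p = 0.234 with an estimated correlation). Monocyte-macrophage-like genes (adjusted p = 0.00159, and adjusted p = 0.234 with an estimated correlation; 2 of 20 over the list alone), proliferation genes (adjusted p = 0.00669, and adjusted p = 0.81 with an estimated correlation), NK cell markers (median -1.91, adjusted p = 6.05e-06, and adjusted p = 0.261 with an estimated correlation) and platelet markers (adjusted p = 0.0262, and adjusted p = 0.202 with an estimated correlation) were lower. With the block alone early response genes were called higher (adjusted p from 0.23 to 0.0363) and red pulp macrophage markers lower (from 0.16 to 0.021). Neither held with block and estimated correlation together (adjusted p = 0.63 and adjusted p = 0.623). The call of Plxdc2 was lost without any 1 of the 4 libraries.

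**Figure D4:**
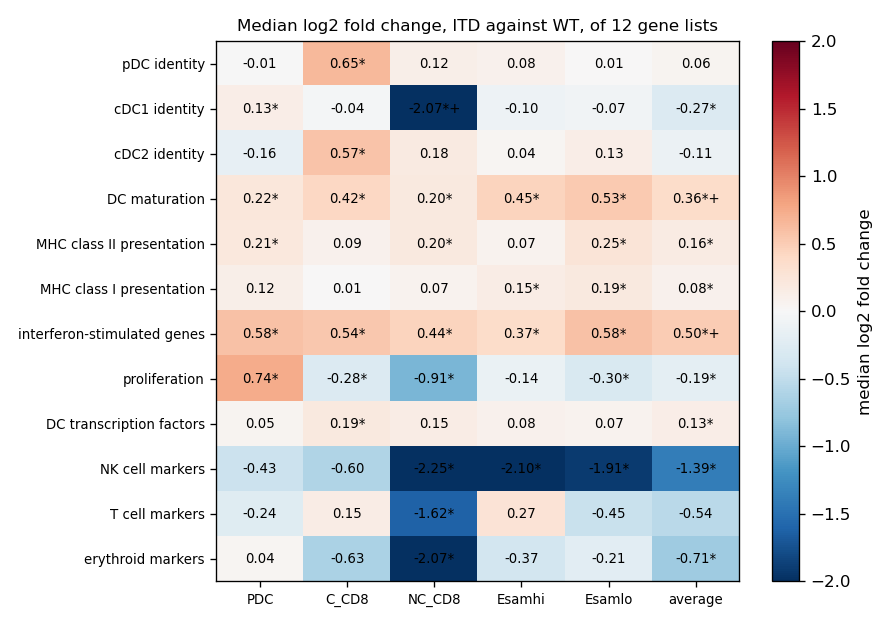
Median log2 fold change of ITD against WT over the members of 12 gene lists (vertical axis) in each subset and on average (horizontal axis), on a colour scale in log2 units from -2 to 2, with a star where camera gave an adjusted p under 0.05 and a plus where this held with an estimated correlation. The medians of DC maturation and interferon-stimulated genes are above 0 in all columns, and that of cDC1 genes is -2.07 in NC_CD8 cells.

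Whether the ITD effect differed among subsets was tested directly. Without a block no gene passed the test over the 5 subsets in edgeR (0 called; 410 genes at an unadjusted p under 0.05; 54 called by DESeq2). The lowest adjusted p was 0.0749, for Socs2, Gm9847 and 1700025G04Rik. With the pair block 55 genes differed, 18 without batch B, 3 without batch C and 30 without batch D, and 5 with the batch block. With 1 pair left out the count ran from 23 (Esamhi D) to 109 (Esamlo C), and it was 27 to 33 without any 1 pair of C_CD8, NC_CD8 C or Esamhi C. Socs2 did so (adjusted p = 0.00162), with log2 effects of 5.45 in PDC, 0.77 in C_CD8, 2.98 in NC_CD8, 0.82 in Esamhi and 1.93 in Esamlo cells. Spib (adjusted p = 0.000571) had effects of -0.22, 1.73, 0.31, 0.49 and 0.67 in the same order. Hes1, a Notch target, had -1.75, 0.07, -1.90, -0.19 and -0.74 (adjusted p = 0.00517). Tcf7 had 0.00, 1.35, -0.72, 0.05 and -0.48 (adjusted p = 0.00692) and Plxdc2 had -0.01, 3.46, 0.59, 1.62 and 2.79 (adjusted p = 0.0402). Lrp8 (adjusted p = 0.00625), Itgb3 (adjusted p = 0.0123), Apoe (adjusted p = 0.029), Gbp7 (adjusted p = 0.0402), Btla (adjusted p = 0.0432), Repin1 (adjusted p = 0.0432) and Gm8221 (adjusted p = 0.000325; 45.1% of its 50-base words shared) differed too. An effect past the threshold in 1 subset and not in another is not shown to differ for other genes. Without a block the count was 16 without NC_CD8 WT replicate 3, 5 without Esamlo WT replicate 1, 3 without Esamhi ITD replicate 2 and 1 without Esamlo WT replicate 2.

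Between the CD8+ subsets, 1 gene passed without a block. Ncf4 fell in NC_CD8 cells relative to C_CD8 cells, by -1.49 on the log2 scale (adjusted p = 0.0497; with the block -1.48, adjusted p = 0.00849), from 47.8 ± 8.67 to 15.9 ± 2.33 CPM (SD, n = 3) against 206 ± 13.2 to 192 ± 9.09 CPM. DESeq2 called 40 genes. With the pair block 117 differed, 21 with a higher and 96 with a lower effect in NC_CD8 cells. The count was 50 without batch B, 29 without batch C and 4 with the batch block, and 43 without the pair NC_CD8 C and 63, 52 and 66 without the C_CD8 pairs B, C and D. Effects were higher for Socs2 (2.21 ± 0.31 SE, adjusted p = 0.0095), Gbp7 (2.25), Pim2 (1.02, adjusted p = 0.0135), Repin1 (1.62) and the lipopeptide receptor Tlr2 (1.09). They were lower for Spib (-1.42 ± 0.12, adjusted p = 0.000454), Tcf7 (-2.08, adjusted p = 0.000528), Cd207 (-3.42), Gcsam (-3.24), the integrin Itgae (-3.23, adjusted p = 0.0095), Tlr3 (-3.23), Siglech (-1.60), Il21r (-1.51), Cd209d (-1.68) and Apoe (-1.11). As a list cDC1 genes had a lower effect in NC_CD8 cells (median -1.81, camera adjusted p = 1.68e-22, and adjusted p = 0.0559 with an estimated correlation; 0 of 20 called, 11 over the list alone, 4 with the block). So did pDC genes (-0.69, adjusted p = 8.42e-07, and adjusted p = 0.101 with an estimated correlation), proliferation genes (adjusted p = 7.1e-06, and adjusted p = 0.61 with an estimated correlation) and markers of T cells (adjusted p = 1.22e-07, and adjusted p = 0.102 with an estimated correlation) and B cells (adjusted p = 0.000761, and adjusted p = 0.436 with an estimated correlation). The lists of cDC2 (adjusted p = 0.0314), monocyte-macrophage-like (0.0227), NK cell (0.0228) and red pulp macrophage genes (0.0179) had lower effects too. None of these held with an estimated correlation (adjusted p = 0.427, adjusted p = 0.422, adjusted p = 0.663 and adjusted p = 0.722). The block called MHC class II genes with a higher effect in NC_CD8 cells (adjusted p from 0.0518 to 0.00392), and transcription factors (from 0.0894 to 0.00434) and cytokine receptors (from 0.331 to 0.00392) with a lower effect. None held with block and estimated correlation together (adjusted p = 0.393, adjusted p = 0.115 and adjusted p = 0.0663). It ended the call of interferon-stimulated genes (from 0.0336 to 0.121). Without a block the count was 16 without NC_CD8 WT replicate 3, 1 without C_CD8 ITD replicate 2 or NC_CD8 ITD replicate 3, and 0 without any other library of these subsets. Ncf4 kept its call without NC_CD8 WT replicate 3 or NC_CD8 ITD replicate 3 and lost it without any other library of these subsets.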

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

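Among the tests of this part, those of canonical marker genes and of single batches in NC_CD8 cells, of the sizes of the falls and rises, and of other splits for the average over subsets were chosen only after the result was seen.

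Ncf4 was singled out because its ITD effect differed between the CD8+ subsets by a test of the difference itself: -1.49 on the log2 scale without a block. By the same kind of test with the pair block, 117 genes had ITD effects that differed between NC_CD8 and C_CD8 cells (29 without batch C, 4 with the batch block). Over all 5 subsets, 55 genes did with that block (3 without batch C, 5 with the batch block).

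Lower cDC1 genes in NC_CD8 ITD cells (16 of 20 with the pair block) were weighed first, and 1 experiment batch is argued against, since the list's median was under 0 in 3 of 3 batches. Fewer canonical CD8+ cells in the ITD gate may account for this list: 100% of 6 canonical marker genes were higher in NC_CD8 WT cells (median implied difference in share 8.78%, 0.809 to 11.2), but 2 of these are in the cDC1 list, and the 4 outside it (4 of 4 higher, median 8.78%) were tested after the fall was seen. The 16 genes need 8.79% at the median, with 2 above every marker, and loss of cDC1 expression within the cells would lower such markers too, so the match does not favour this explanation. Of the other 419 falls, 80.7% need a larger share than any of 6 markers gave or were lower in C_CD8 WT cells. The 419 were picked for falling and hold NK, T and erythroid markers, whose loss was not weighed, so this test decides no cause. Nor do the 13.4% (95% exact interval 10.3 to 17) lower in C_CD8 WT than in NC_CD8 ITD cells. For the cDC1 genes an effect within the cells and a gate change both stay open, as bulk RNA cannot separate them.

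Higher NC_CD8 genes in C_CD8 ITD cells were weighed next. More non-canonical CD8+ cells in the ITD gate may account for part of them: 100% of 26 NC_CD8 marker genes were higher in C_CD8 ITD than in WT cells, and 4.19% of the 215 genes that rose with the pair block (95% exact interval 1.93 to 7.8) were lower in NC_CD8 ITD cells. The 26 were picked on WT and ITD levels in C_CD8 cells together, which limits the share they can imply, so the share was taken from 49 genes picked on WT levels alone (median 3.99%, at most 23%, for Ptgs2). The size of the rise does not decide whether more non-canonical cells are the whole cause. Of the 215 genes, 49.3% need more than 23% or were lower in NC_CD8 ITD cells, while the others stay within 23%. The 215 were picked for rising, however, which favours large shares. An effect of the mutation stays open and was not tested apart from the sort.

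Pancreatic transcripts in PDC WT libraries were weighed last. RNA of pancreatic acinar cells in the libraries may be the source: over 20 acinar genes, listed before the test, the 2 PDC WT libraries correlated across genes at r = 0.929, and the genes are not independent. Amy2a5 (33.6 and 156 CPM; 53.5% of its 50-base words shared with other genes, mostly Amy2a2), Pnlip (12.5 and 100 CPM) and Prss2 (7.47 and 70.7 CPM) were abundant in them. The sum was higher in WT in 9 of 12 pairs, both PDC pairs included, so the genotype stays open as well. The sort would remove acinar cells but not their free RNA.

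Other splits of the libraries were counted where enough libraries allowed them. On average over the 5 subsets, 3 of 100 splits gave at least the real 65 genes, the real one included. The highest other split gave 258 and points to a structure of the samples: it parted 6 of the 12 pairs. The 7 others that parted 12 pairs gave 0 and are too few to exclude chance. With the pair block 1 of 50 gave as many (1236; the highest other, 4), excluding chance only if pairs of 1 batch are independent. Between the CD8+ subsets 6 of 60 gave at least the real 1 gene, so chance is not excluded. The highest other gave 956 and points to a structure as well: it parted 8 pairs, and the 4 others that parted 12 gave 0. For the ITD effect in C_CD8 cells (3; the highest other, 2), in NC_CD8 cells (56; the highest other, 1) and for NC_CD8 against C_CD8 cells in WT (4528; the highest other, 0), 1 of 10 splits gave as many, and 10 are too few for a share under 0.05.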

How the results depend on the processing

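Alternatives for the fit with the pair block, fits without batch B and the block joined with an estimated correlation were chosen after the data were seen. No call of a named gene reversed: 0 of 1145 values, 284 called, did under RLE, no filter, DESeq2 or the batch block, 0 of 790 with the pair block, and 0 of the 223 to 587 values fitted with each library left out. Signs changed without a call for 3 values with the pair block, 1 with the batch block and at most 16 with a library left out (either PDC WT library). RLE size factors kept every count within 1.5 times except that of Esamlo with the pair block (14 against 9). The pair block turned 218 of the 790 values into calls and ended 0 of them, but it ended the PDC calls of Sspo and Pvt1, which are not among the 790.

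Counts are given without a block in the order PDC, C_CD8, NC_CD8, average, among 5 subsets, and NC_CD8 against C_CD8 effects. The main counts of 11, 3, 56, 65, 0 and 1 became 18, 13, 86, 99, 2 and 0 with no filter on low counts, 18, 98, 227, 293, 54 and 40 with DESeq2, 45, 223, 866, 1236, 55 and 117 with the pair block, and 40, 118, 572, 849, 5 and 4 with the experiment batch as a block. The Esamhi and Esamlo counts of 0 and 1 became 2 and 2 with DESeq2, 9 and 9 with the pair block, and 1 and 2 with the batch block. Among WT subsets, NC_CD8 against C_CD8 (4528) and against PDC (4777) gave 7603 and 7870 with the batch block, and Esamhi against Esamlo (119) gave 1151 with it and 437 with DESeq2. Fits on the 2 compared groups alone gave 0 in PDC, C_CD8 and Esamlo, 3 in NC_CD8 (0 of the 56) and 11 for Esamhi against Esamlo. Without batch B, the counts were 0 in C_CD8, 121 in NC_CD8 and 121 on average, 46 of the last shared with the 65.

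With each library left out, counts ran from 4 to 8 in PDC, 0 to 23 in C_CD8, 4 to 83 in NC_CD8, 0 to 0 in Esamhi and Esamlo, 38 to 79 on average, 0 to 16 among subsets and 0 to 16 between the CD8+ subsets. They ran from 3024 to 4052 for NC_CD8 against C_CD8, 3260 to 4351 against PDC and 4 to 126 for Esamhi against Esamlo in WT. Fewer libraries are part of the cause there, and beyond that the cause was not tested.

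The counts with the pair block, in the same order, changed further with DESeq2, to 118 in PDC, 440 in C_CD8, 64 in Esamhi, 236 in Esamlo, 519 among subsets and 316 between the CD8+ subsets. With no filter they were 96, 352, 31, 90, 310 and 272. With each pair left out they ran from 8 (batch B) to 16 (A) in PDC, 86 (B) to 143 (D) in C_CD8, 244 (C) to 654 (B) in NC_CD8, 0 to 0 in Esamhi, 3 (D) to 127 (C) in Esamlo, 549 (Esamhi D) to 1273 (NC_CD8 B) on average, 23 (Esamhi D) to 109 (Esamlo C) among subsets, and 43 (NC_CD8 C) to 129 (NC_CD8 D) between the CD8+ subsets. Without all of batch B, C or D the average gave 483, 430 and 418 and the test among subsets 18, 3 and 30, and without B or C the test between the CD8+ subsets gave 50 and 29. The cause was not tested for any of these changes.

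Of 260 list tests, camera called 99, of which 10 were called with an estimated correlation. Fry called 33 (28 shared), the block 104 (88 shared), the block with an estimated correlation 31 (29 shared) and RLE 99 (98 shared), none in the opposite direction. Apart from the gene and list calls given with it, the block ended no other call of a list and no other call of a gene in a genotype comparison. Depth limits genes of few reads, whose folds are lower bounds where 1 group had none, and 2 libraries per group limit PDC, Esamhi and Esamlo, where the simulation without a block recovered 28%, 32% and 38% of genes changed 2-fold.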

Other observations

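The hypothesis on the Flt3 flank was tested by a test fixed before its result was seen, and the genes named in the first paragraphs were chosen after their values were seen.

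MAPK feedback targets, genes that growth factor signalling through ERK induces and of which only some restrain it, were lower in ITD cells on average (camera adjusted p = 0.00412; adjusted p = 0.066 with an estimated correlation). Without a block 0 of 19 were called, 4 were lower with p adjusted over the list alone, and 4 fell with the pair block: Dusp6 (-0.82, adjusted p = 0.000301; lower in 12 of 12 pairs), Spry2 (-1.45, adjusted p = 0.0242), the transcription factor Etv5 (-0.83, adjusted p = 0.00885; higher in 2 of 12 pairs) and Ccnd1 (-0.44, adjusted p = 0.00658). The BCL2 family was not called on average (adjusted p = 0.605, and adjusted p = 0.292 with the block). Of its 13 members, the pro-apoptotic genes Bcl2l11 (0.38, adjusted p = 0.00254) and Pmaip1 (0.36, adjusted p = 0.0113) rose on average with the block, and in NC_CD8 cells the survival gene Bcl2a1b (0.81, adjusted p = 0.00509) did too.

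T cell-directed cytokines and ligands were called higher on average with the block (adjusted p = 0.0079, and adjusted p = 0.38 with an estimated correlation as well), with Cxcl16 (0.55, adjusted p = 0.000407) and Tnfsf9, the ligand of 4-1BB (0.74, adjusted p = 0.00604), among the 9 that rose. Cytokine receptors were not called (adjusted p = 0.308 with the block), with 3 up and 2 down, Il7r (0.69, adjusted p = 0.00412) and Il2rg (0.31, adjusted p = 0.00979) among those up. In NC_CD8 cells the cytokine Il15 (-1.46, adjusted p = 0.0146) fell. Further average falls with the block were those of Prss2 (-4.10, adjusted p = 0.00973), a pancreatic gene, Il2rb (-1.66, adjusted p = 0.00268; lower in 12 of 12 pairs), Hpgd (-1.53, adjusted p = 0.00134) and Ace (-1.33, adjusted p = 0.00412). Il2rb is also expressed by NK cells, whose markers were lower in ITD libraries.

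DNA that flanks the Flt3 allele could differ between the genotypes and change the expression of genes near it, Fscn1 among them (4.37 Mb away on the same chromosome). Of 272 tested genes within 20 Mb of Flt3, 23 (8.46%) were called on average with the pair block, against 1207 of 17564 others (6.87%). The odds ratio was 1.25 (95% interval 0.776 to 1.93; Fisher's exact test, two-sided, p = 0.333), which leaves the hypothesis undecided.

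Xist, expressed from the inactive X chromosome of females, was higher in ITD than in WT cells of each pair from batches A and B: 90.8 CPM in WT and 235 CPM in ITD PDC cells of batch A, 270 and 366 CPM in those of batch B, 49.6 and 131 CPM in C_CD8 cells, and 34.5 and 205 CPM in NC_CD8 cells. It had 0 reads in the CD8+ libraries from batches C and D. In the PDC libraries of batch A the Y-linked genes were at lower levels in ITD: Kdm5d at 28.9 CPM in WT and 14.7 CPM in ITD, Ddx3y at 212 and 158 CPM and Eif2s3y at 102 and 71.9 CPM. In those of batch B each was at most 0.197 CPM. Sex and any pooling of the mice are not given in the sources. Sex is not separated from genotype in the PDC pair of batch A and the CD8+ pairs of batch B.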
